A study of Arabidopsis thaliana with 6 samples.

How the data were processed

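Transcript levels were measured by RNA sequencing (Illumina) in 6 libraries of wild-type Arabidopsis seedlings, 2 for each of 3 groups: solvent control, 1 nM IAA and 10 nM MT, all at 72 h. Groups and replicate numbers were taken from the sample labels, whose titles call the control group 72 h without treatment. The deposited values are raw counts of reads per gene in 1 table for the whole series. Per the submitters' processing notes the tools used were TopHat2 2.0.12, Bowtie2 2.2.3, HTSeq 0.6.1 and DESeq 1.18.0, with no statement of how each was set. The genome build, the annotation and whether reads were counted by strand are not given in the sources used here. So no coordinates are given, and genes that overlap another gene on either strand can share reads. RNA was extracted with a column kit, per the labels' protocols.

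The table held 24267 genes with at least 1 count, of which 23606 matched a locus tag of the TAIR10.1 annotation, used here only for gene symbols and for which genes neighbour or overlap each other. A further 351 entries were named as new genes and were kept in library sizes and tests. They took 0.293 to 0.337% of counts in the control and IAA libraries, 0.189% in MT replicate 1 and 0.357% in MT replicate 2. Library totals were 35953236 to 46076624 counts and chloroplast-encoded genes took 0.0105 to 0.0190% of them. Replicates differed far beyond counting noise, with a chi-square over its degrees of freedom of 25.6 to 32.8 over genes with at least 20 counts. Their log CPM correlated across genes with r from 0.977 to 0.981, so each library was counted as a sample. For how many genes the spread between libraries exceeded counting error was not counted. The common biological coefficient of variation was 16.1%. Counting intervals given for single genes cover counting error only.

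Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group (21355 genes kept), and the quasi-likelihood test over all 6 libraries with group as the only term, which left 3 residual degrees of freedom (prior degrees of freedom 3.83). The p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with 0.05 as threshold, and every adjusted p of a gene in the text is from this test unless another is named. The comparisons made were IAA with control, MT with control and MT with IAA. Values per group are CPM with TMM-scaled library sizes, as mean ± SD of 2 libraries, and values after a gene without a unit are log2 fold changes ± SE. Gene lists were tested with limma 3.58.1 camera on voom values at a preset correlation between genes of 0.01, adjusted over the 32 lists with at least 5 tested members. Where members are counted as adjusted over the list alone, p-values of edgeR's test were adjusted within that list and not across the 32 lists. Members of a list can be correlated, so these counts are not of independent genes. A list was also tested with an estimated correlation, with which 0 lists were called in each comparison. Another test, fry, asks whether the genes of a list move one way on balance, and called 2, 13 and 1 lists. With MT against control fry did not call the hypoxia, endodermis, clock, jasmonate, SAUR, cytokinin and cell cycle lists, which camera called. It did call the melatonin list (fry adjusted p = 0.0186), which camera did not.

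The 33 lists, with 586 members in those written by symbol, covered auxin (Aux/IAA repressors, GH3 and LBD genes, SAUR genes, receptors and response factors, transport, synthesis and inactivation), other hormones, melatonin, stress and nutrient responses, photosynthesis, clock, cell cycle, cell wall, root tissues, secondary metabolism, seed storage, and the chloroplast- and mitochondria-encoded genes. The lists, the rule for named genes and the alternatives were fixed before the data were examined. For 2 members the gene identifier was replaced by that of the annotation and for 19 the symbol was not paired with the identifier, which then decided. Of the seed storage list 10 members had counts, at most 97 in a library, and 3 were tested with 0 called in any comparison, so the list was not tested.

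Genes were named by this rule: per comparison, among called genes with a mean of at least 2 CPM and no overlap between the libraries of the groups compared, the 10 with the highest and the 10 with the lowest log2 fold change. It added up to 4 members with the smallest p of each list called. It also named, called or not, IAA5, IAA19, GH3.3, LBD29, PIN3, PIN7, AUX1, TAA1 and CCA1, the sentinels, and 1 more gene that is not reported here. Not all list members that the rule allows were named, and which were taken was decided after their values were seen. Named outside the rule, after their values were seen, were LHCB2.3, LHCB1.2, LHCB3 and RBOHD with IAA. With MT they were RBOHD, LNK1, BHLH101, GH3.2, GH3.5, YUC5, ASA1, PID, ABCB1, ABCB19, PILS3, PILS5, ARF10, ERF1, ACS8, CBP60G, SAG101, CAT1, CAT3, COR15A, P5CS1, RAB18, XTH16, DIN1 and IMD1. Clock genes by phase were added, and AT1G15670, CYP89A2, AT5G01881 and AT5G17760, which differed between the compounds with opposite signs against control. Genes of the text whose models overlap another gene, and whose counts are therefore uncertain, were ASN1, AT1G27695, DIN10, GDPD6, IAA5, PAP17, PAP24, PP2-B13, UGT74F2, ABCC7, ADH1, AT4G23440, AT5G57760, BCAT-2, CASP5, EBF2, ICME-LIKE2, LHCB2.3 and LHCB3. So were LHT7, SHY2, TCH2, CRK10, AT5G01881, LNK1, BHLH101, ABI1, PILS5, ASA1, P5CS1, RAB18, IMD1, BCAT4, F3H, XTH15, MYC2, COR15B and CDKB2;2.

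The effect of shared controls was simulated 50 times: counts of all 6 libraries were drawn for unchanged groups, each gene independently. Both comparisons then used the same 2 drawn control libraries. In a further fit each control library served as the control of a single comparison, both ways round, with the dispersions of the main fit. The gene test was checked on simulated counts of 21355 genes with 200 changed. In the comparison of IAA with control it recovered 20.9, 50.7 and 86.4% of genes changed 1.5-, 2- and 4-fold, and 11.8% of its 119 calls (14) were unchanged genes, above the nominal share. For MT with control it recovered 16.4, 58.2 and 80.3%, and 12.7% of its 118 calls (15) were unchanged genes. With all 12 phosphate genes shifted 2-fold, camera with the preset correlation called that list and 0 others. The estimated correlation gave it adjusted p of 0.119 (IAA) and 0.059 (MT), so that setting missed a simulated shift. The simulated genes were drawn independently, whereas the estimated correlation was 0.899 in the hypoxia list (IAA against control). The check therefore does not show how often the preset correlation calls a correlated list falsely. Tests of single explanations used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3: Fisher's exact test, two-sided, and permutation tests with 100000 permutations. Figures were drawn with matplotlib 3.10.9.

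Alternatives were relative log expression and upper quartile factors, no low-count filter, a filter of at least 1 CPM in at least 2 libraries, robust empirical Bayes, DESeq2 1.42.0, a fit of only the 2 groups compared, the replicate number as a block, organelle-encoded genes left out, other thresholds, and leaving out each library in turn. With a library left out its partner stood alone and was assumed to vary like the other groups, and the fit had fewer residual degrees of freedom. Among lists that were not called, the median, the mean and the direction of the test differed in sign for 7 with IAA against control, 2 with MT against control and 3 with MT against IAA, and for 0 of the lists called.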

Results

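RNA from wild-type Arabidopsis thaliana (Columbia) was sequenced after young seedlings had spent 72 h on medium with ethanol alone as solvent control, with 1 nM indole-3-acetic acid (IAA, the main natural auxin) or with 10 nM melatonin (MT). Plants make both compounds, which are indoles, from tryptophan, and their doses were not matched. The sample labels describe seedlings, whereas the design text of the series speaks of rosette leaves, so the tissue is given here only as the labels have it. All 17 root hair and 24 endodermis genes listed had enough counts to be tested. The root hair genes with the smallest p with IAA had 17.8 to 76.2 CPM in the control. These values argue against rosette leaves alone. Each group had 2 libraries. Counts summed to 36023731 and 38186518 in the control libraries, 43662338 and 46076624 with IAA, and 35953236 and 39528975 with MT. No source used here says that the libraries of a group came from separate cultures or pools, so the p-values measure only the spread between these samples, which may be technical.

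The first comparison, IAA with control, asked which transcripts a low dose of auxin changed. Genes of the phosphate starvation response rose with IAA: 8 of 12 measured members rose, 0 fell and 4 did not pass. SPX1 (AT5G20150), an inhibitor of phosphate starvation signalling that the response itself induces, went from 22.8 ± 0.996 to 98.2 ± 14.9 CPM (mean ± SD, n = 2 libraries each). Its log2 fold change was 2.11 ± 0.12 (SE), with an adjusted p of 0.00356 in edgeR's quasi-likelihood test. SPX3 (AT2G45130) rose by 2.76 ± 0.32, MGDC (AT2G11810), which makes galactolipids that replace phospholipids, by 2.76 ± 0.23, and the acid phosphatase PAP17 (AT3G17790) by 1.25 ± 0.10. Over the 21355 genes tested 58 rose and 13 fell, and 38 of the risen and 4 of the fallen changed at least 2-fold.

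Among the genes of at least 2 CPM with the largest rises, PAP5 (AT1G52940) (3.43 ± 0.39), PAP24 (AT4G24890) (2.40 ± 0.19) and PAP14 (AT2G46880) (2.36 ± 0.26) are purple acid phosphatases. GDPD6 (AT5G08030) (3.22 ± 0.30) is a glycerophosphodiester phosphodiesterase and PEPC1 (AT1G17710) (3.00 ± 0.23) a phosphatase. These 5 genes are not in the phosphate list tested below. AT3G25240 rose by 2.74 ± 0.28 and PP2-B13 (AT1G56240), a phloem protein, by 2.67 ± 0.28. GDPD6, PAP24, PAP17 and PP2-B13 overlap other gene models, so their counts are uncertain. SDR3 (AT2G47130), a dehydrogenase, had the highest fold change among genes with a mean of at least 2 CPM, 7.46 ± 0.77 with an adjusted p of 0.028. Its counts summed to 6 in the control libraries, 3 in each, and to 1358 with IAA, 899 in replicate 1 and 459 in replicate 2. The ratio was 187 (95% counting interval 85.8 to 510.9). Without IAA replicate 1 its log2 fold change was 6.82, and with robust empirical Bayes its call was lost (adjusted p = 0.0534).

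Of the genes of at least 2 CPM that fell, Phox2 (AT1G62390) had the largest change, from 116 ± 15.0 to 28.2 ± 0.833 CPM (-2.05 ± 0.10, adjusted p = 0.00356). ATN (AT3G05330) (-1.93 ± 0.20), AT1G27695 (-1.93 ± 0.22), AT3G50560 (-1.51 ± 0.19) and AT3G11930 (-0.96 ± 0.12) fell. So did the antenna gene LHCB4.3 (AT2G40100) (-0.91 ± 0.08), RVE2 (AT5G37260) (-0.91 ± 0.11), the sugar carrier SWEET2 (AT3G14770) (-0.90 ± 0.11) and MES16 (AT4G16690) (-0.71 ± 0.09). The salicylate glucosyltransferase UGT74F2 (AT2G43820) fell too (-0.74 ± 0.10). Its call was lost with relative log expression factors (adjusted p = 0.0501) and with upper quartile factors (adjusted p = 0.0523). With the replicate number as a block the calls of UGT74F2, AT1G27695, AT3G11930, RVE2, SWEET2 and MES16 were lost (adjusted p from 0.0531 to 0.0848).

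Of 32 lists of genes, 8 were higher and 1 lower with IAA than control in camera's test. Of these, fry called the phosphate and carbon starvation lists (fry adjusted p = 0.0424 each) and not the others. The phosphate list had a median of 1.09 and, adjusted over the list alone, 11 rose and 0 fell. Camera gave the phosphate list an adjusted p of 3.32e-17, and adjusted p = 0.321 with an estimated correlation. In the hypoxia list 1 of 11 measured members rose, 0 fell and 10 did not pass. Its median was 1.42 and, adjusted over the list alone, 10 rose and 0 fell. The estimated correlation of the members was 0.899, so these 10 are not independent. Camera gave the hypoxia list an adjusted p of 2.72e-13, and adjusted p = 0.41 with an estimated correlation. The member that rose was SUS4 (AT3G43190), a sucrose synthase (2.32 ± 0.21). HB1 (AT2G16060), a haemoglobin, had 1.41 ± 0.19 (adjusted p = 0.0506) and the pyruvate decarboxylase PDC1 (AT4G33070) had 1.75 ± 0.25 (0.0558). In the touch and wounding list 0 of 11 members passed over all genes. Its median was 0.86 and, adjusted over the list alone, 7 rose and 0 fell. Camera gave the touch list an adjusted p of 2.96e-05, and adjusted p = 0.41 with an estimated correlation. In the carbon starvation list 0 of 5 members passed over all genes. Its median was -0.79 and, adjusted over the list alone, 0 rose and 5 fell. Camera gave the carbon starvation list an adjusted p of 2.13e-06, and adjusted p = 0.321 with an estimated correlation. DIN10 (AT5G20250) had -0.64 ± 0.09 and the asparagine synthetase ASN1 (AT3G47340) had -1.45 ± 0.33. Without either MT library HB1, PDC1, DIN10 and ASN1 were called (adjusted p from 0.0189 to 0.0499).

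In the ethylene list 2 of 21 measured members rose, 0 fell and 19 did not pass. Its median was 0.19 and, adjusted over the list alone, 2 rose and 0 fell. Camera gave the ethylene list an adjusted p of 0.0176, and adjusted p = 0.41 with an estimated correlation. Those that rose were ETR2 (AT3G23150) (0.96 ± 0.08), a receptor, and ACO1 (AT2G19590) (1.45 ± 0.17), an enzyme of ethylene synthesis. The lists of root hair (17 members), flavonoid (20), glucosinolate (25) and cell cycle genes (24) had 0 members past the threshold over all genes. The root hair list had a median of 0.33 and, adjusted over the list alone, 4 rose and 0 fell. Camera gave the root hair list an adjusted p of 1.22e-06, and adjusted p = 0.472 with an estimated correlation. The flavonoid list had a median of 0.38 and, adjusted over the list alone, 1 rose and 0 fell. Camera gave the flavonoid list an adjusted p of 0.00155, and adjusted p = 0.41 with an estimated correlation. The glucosinolate list had a median of 0.11 and, adjusted over the list alone, 5 rose and 0 fell. Camera gave the glucosinolate list an adjusted p of 0.0028, and adjusted p = 0.41 with an estimated correlation. The cell cycle list had a median of 0.11 and, adjusted over the list alone, 0 rose and 0 fell. Camera gave the cell cycle list an adjusted p of 0.0177, and adjusted p = 0.808 with an estimated correlation. In these 4 lists and those of touch and carbon starvation, 37 of 102 members had an unadjusted p under 0.05 in edgeR's test and DESeq2 called 19. Of all 21355 genes tested 3047 had an unadjusted p under 0.05 with IAA. Without control replicate 1 the adjusted p was 0.0639 for both the ethylene and the cell cycle list. Without IAA replicate 1 it was 0.461 for the cell cycle and 0.0662 for the flavonoid list. Of the photosynthesis list 3 antenna genes rose, LHCB2.3 (AT3G27690) (1.15 ± 0.11), LHCB1.2 (AT1G29910) (1.11 ± 0.14) and LHCB3 (AT5G54270) (0.70 ± 0.09). Adjusted over the list alone 7 of 36 rose and 3 fell, its median was -0.024, and the list was not called (adjusted p = 0.735). The other 22 lists were not called either, with adjusted p from 0.0702 to 0.997.

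With IAA 0 of 126 measured members of the 6 lists of auxin genes passed over all genes in edgeR's test, while 22 had an unadjusted p under 0.05 and DESeq2 called 3. Of all 21355 genes tested 3047 had an unadjusted p under 0.05, so the auxin lists stood near the share of all genes. The adjusted p of these lists ran from 0.203 to 0.803. Of the sentinels, GH3.3 (AT2G23170), an IAA-conjugating enzyme, had -0.56 ± 0.18 (adjusted p = 0.262) and the repressor gene IAA19 (AT3G15540) had -0.55 ± 0.21 (0.319). IAA5 (AT1G15580) had 0.31 ± 0.46 (0.806) and LBD29 (AT3G58190) had 0.39 ± 0.42 (0.723). Among auxin carriers PIN3 (AT1G70940) had -0.31 ± 0.10 (0.268), PIN7 (AT1G23080) 0.32 ± 0.15 (0.385) and AUX1 (AT2G38120) 0.08 ± 0.08 (0.701). TAA1 (AT1G70560), of auxin synthesis, had 0.28 ± 0.20 (0.574) and the clock gene CCA1 (AT2G46830) -0.47 ± 0.21 (0.382). Of these 9 sentinels 3 had an unadjusted p under 0.05 and DESeq2 called 0.

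The count of 71 genes was 19 without control replicate 1, 25 without control replicate 2, 22 without IAA replicate 1, 14 without IAA replicate 2, 114 without MT replicate 1 and 120 without MT replicate 2, and DESeq2 gave 768. Of the 30 named genes called with IAA, SPX1 and Phox2 passed with each library left out, while the others reached adjusted p from 0.0593 to 0.230 without a control or IAA library.

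**Figure D1:**
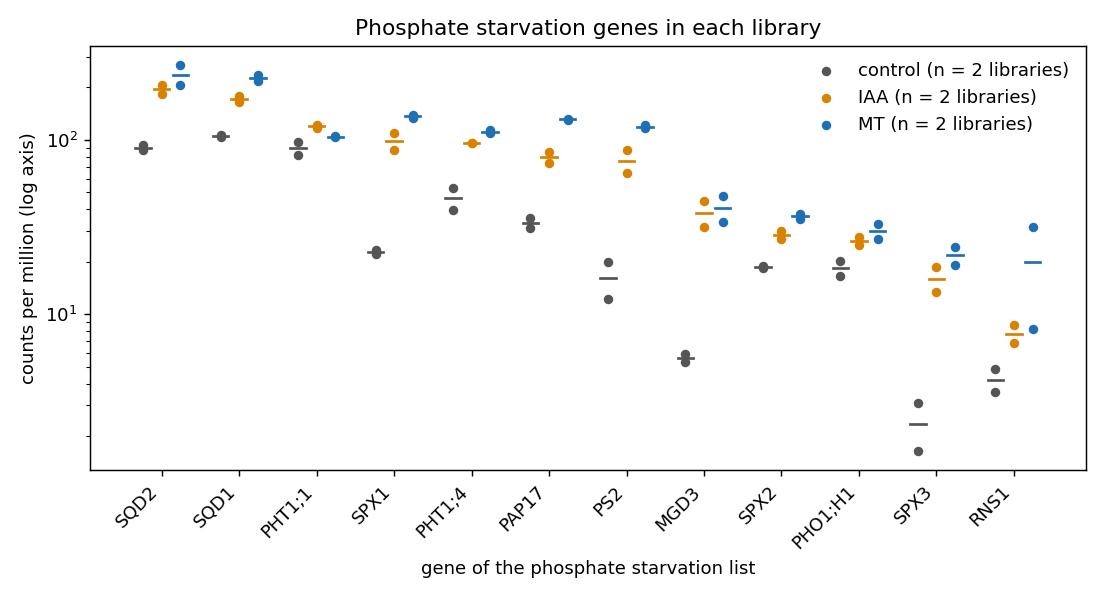
CPM (log axis) of the 12 measured genes of the phosphate starvation list, with a point per library (2 each of control, IAA and MT) and a bar at each group mean. The mean of SPX1 went from 22.8 in the control to 98.2 with IAA and 137 with MT, and the points of RNS1 with MT lie far apart.

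The comparison of MT with control asked which transcripts melatonin changed at the dose used. With MT 853 genes rose and 780 fell, 1633 of 21355 tested, and 323 of the risen and 132 of the fallen changed at least 2-fold (edgeR's quasi-likelihood test). In the phosphate starvation list 10 of 12 measured members rose, 0 fell and 2 did not pass. SPX1 rose from 22.8 ± 0.996 to 137 ± 3.74 CPM (n = 2 each, 2.58 ± 0.12, adjusted p = 0.00151), PAP17 by 1.97 ± 0.10, MGDC by 2.85 ± 0.23 and the sulfolipid synthesis gene SQD1 (AT4G33030) by 1.11 ± 0.09. All 5 measured members of the carbon starvation list fell, among them ASN1, from 178 ± 36.9 to 29.6 ± 14.5 CPM (-2.59 ± 0.35, adjusted p = 0.00942). Without MT replicate 2 ASN1 had -3.19, and with robust empirical Bayes its adjusted p was 0.0605.

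Nuclear genes of photosynthesis were higher with MT: 16 of 36 measured members rose, 0 fell and 20 did not pass. Its median was 0.35 and, adjusted over the list alone, 22 rose and 2 fell. Camera gave the photosynthesis list an adjusted p of 2.07e-11, and adjusted p = 0.34 with an estimated correlation. They included LHCB2.3 (2.04 ± 0.11), LHCB3 (1.39 ± 0.09), LHCB1.2 (1.95 ± 0.14) and the Rubisco small subunit gene RBCS3B (AT5G38410) (0.92 ± 0.09). Members of the LHCB1 and RBCS families are near-identical copies among which reads could be split, so their single values are uncertain. In the list of root endodermis, suberin and stele genes 0 of 24 measured members rose, 7 fell and 17 did not pass. Its median was -0.52 and, adjusted over the list alone, 1 rose and 14 fell. Camera gave the endodermis list an adjusted p of 3.70e-06, and adjusted p = 0.474 with an estimated correlation. The triterpene gene MRN1 (AT5G42600) had -1.90 ± 0.17, CASP5 (AT5G15290), a Casparian strip protein, -1.27 ± 0.21, and TIP2;3 (AT5G47450), an aquaporin, -0.95 ± 0.12.

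In the touch and wounding list 8 of 11 measured members rose, 0 fell and 3 did not pass. Its median was 1.77 and, adjusted over the list alone, 10 rose and 0 fell. Camera gave the touch list an adjusted p of 3.60e-08, and adjusted p = 0.203 with an estimated correlation. STZ (AT1G27730) rose by 2.25 ± 0.26, SZF1 (AT3G55980) by 2.11 ± 0.19 and the calmodulin-like TCH2 (AT5G37770) by 0.80 ± 0.08. In the hypoxia list 8 of 11 measured members rose, 0 fell and 3 did not pass. Its median was 1.13 and, adjusted over the list alone, 10 rose and 1 fell. Camera gave the hypoxia list an adjusted p of 1.08e-05, and adjusted p = 0.421 with an estimated correlation. SUS4 rose by 1.92 ± 0.21 and the alcohol dehydrogenase ADH1 (AT1G77120) by 1.47 ± 0.26, a call lost with robust empirical Bayes (adjusted p = 0.0646). The phosphate list had a median of 1.68 and, adjusted over the list alone, 11 rose and 0 fell. Camera gave the phosphate list an adjusted p of 1.17e-13, and adjusted p = 0.203 with an estimated correlation. The carbon starvation list had a median of -1.92 and, adjusted over the list alone, 0 rose and 5 fell. Camera gave the carbon starvation list an adjusted p of 2.98e-07, and adjusted p = 0.203 with an estimated correlation. Beside ASN1 its members were DIN10 (-1.92 ± 0.10), BCAT-2 (AT1G10070) (-1.94 ± 0.17), DIN2 (AT3G60140) (-1.66 ± 0.19) and DIN1 (AT4G35770) (-0.99 ± 0.17).

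Of 25 genes of glucosinolate synthesis 5 rose and 0 fell with MT. They were MYB51 (AT1G18570) (1.97 ± 0.23), a regulator of indole glucosinolates, CYP81F2 (AT5G57220) (1.57 ± 0.20), CYP83A1 (AT4G13770) (0.88 ± 0.11), BCAT4 (AT3G19710) (0.76 ± 0.10) and IMD1 (AT5G14200) (0.56 ± 0.09). The glucosinolate list had a median of 0.41 and, adjusted over the list alone, 12 rose and 0 fell. Camera gave the glucosinolate list an adjusted p of 1.42e-06, and adjusted p = 0.203 with an estimated correlation. Of 20 genes of phenylpropanoid and flavonoid synthesis 3 rose and 0 fell, F3H (AT3G51240) (0.49 ± 0.10) and the anthocyanin regulators AT1G56650 (1.85 ± 0.39) and MYB90 (AT1G66390) (3.41 ± 0.79). Without MT replicate 1 MYB90 had 2.77. The flavonoid list had a median of 0.47 and, adjusted over the list alone, 12 rose and 0 fell. Camera gave the flavonoid list an adjusted p of 2.80e-06, and adjusted p = 0.203 with an estimated correlation. In the cell wall list, of expansins and xyloglucan hydrolases, 0 of 23 measured members rose, 5 fell and 18 did not pass. Its median was -0.24 and, adjusted over the list alone, 2 rose and 7 fell. Camera gave the cell wall list an adjusted p of 0.00347, and adjusted p = 0.203 with an estimated correlation. XTH33 (AT1G10550) (-1.63 ± 0.11), XTH24 (AT4G30270) (-1.72 ± 0.18), XTH4 (AT2G06850) (-0.90 ± 0.14), XTH15 (AT4G14130) (-0.62 ± 0.12) and XTH16 (AT3G23730) (-0.86 ± 0.19) fell, the last not with robust empirical Bayes (adjusted p = 0.06215).

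In the ethylene list 9 of 21 measured members rose, 1 fell and 11 did not pass. Its median was 0.28 and, adjusted over the list alone, 12 rose and 3 fell. Camera gave the ethylene list an adjusted p of 0.0049, and adjusted p = 0.203 with an estimated correlation. ETR2 (1.35 ± 0.08), EBF2 (AT5G25350) (2.07 ± 0.27) and the synthesis gene ACS6 (AT4G11280) (1.65 ± 0.23) rose and ACS8 (AT4G37770) fell (-1.51 ± 0.31). ERF1 (AT3G23240) rose by 3.53 ± 0.59 on 11 counts in the control and 130 in the MT libraries, and had 4.34 without control replicate 2. In the clock list 8 of 19 measured members rose, 0 fell and 11 did not pass. Its median was 0.33 and, adjusted over the list alone, 10 rose and 0 fell. Camera gave the clock list an adjusted p of 0.00688, and adjusted p = 0.474 with an estimated correlation. GI (AT1G22770) rose by 2.05 ± 0.27, PRR3 (AT5G60100) by 1.32 ± 0.10, PRR7 (AT5G02810) by 0.71 ± 0.09 and TOC1 (AT5G61380) by 0.68 ± 0.09. CCA1 had -0.22 ± 0.21 (adjusted p = 0.576), and without MT replicate 1 it had -0.62 and was called (adjusted p = 0.0493). Without that library the adjusted p of the clock list was 0.178.

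Auxin genes went both ways with MT. GH3.3 fell from 39.7 ± 0.0207 to 12.7 ± 1.34 CPM (-1.65 ± 0.19, adjusted p = 0.00664), GH3.2 (AT4G37390) fell (-0.85 ± 0.13) and GH3.5 (AT4G27260) rose (0.80 ± 0.11). That list of GH3 and LBD genes was not called (adjusted p = 0.747) and had a median of -0.22 beside a mean of 0.03. Of 28 Aux/IAA repressor genes 0 rose and 3 fell, IAA19 (-1.31 ± 0.22), SHY2 (AT1G04240) (-0.66 ± 0.10) and IAA16 (AT3G04730) (-0.49 ± 0.08). The Aux/IAA list had a median of -0.10 and, adjusted over the list alone, 1 rose and 9 fell. Camera gave the Aux/IAA list an adjusted p of 0.0318, and adjusted p = 0.291 with an estimated correlation. Of 27 SAUR genes 0 rose and 3 fell, AT4G38840 (-1.15 ± 0.20), AT4G38860 (-0.64 ± 0.13) and AT1G72430 (-0.37 ± 0.07). The SAUR list had a median of -0.31 and, adjusted over the list alone, 0 rose and 5 fell. Camera gave the SAUR list an adjusted p of 0.00923, and adjusted p = 0.421 with an estimated correlation. Without MT replicate 2 the adjusted p of the Aux/IAA list was 0.0724, and without control replicate 2 that of the SAUR list was 0.0775.

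Among auxin transport genes PIN7 rose (1.03 ± 0.15), as did ABCB1 (AT2G36910) (0.40 ± 0.09), ABCB19 (AT3G28860) (0.47 ± 0.10) and the kinase gene PID (AT2G34650) (0.92 ± 0.18). PIN3 (-0.55 ± 0.11), PILS3 (AT1G76520) (-0.52 ± 0.09) and PILS5 (AT2G17500) (-0.78 ± 0.14) fell. With the replicate number as a block the calls of ABCB1 (adjusted p = 0.0543) and ABCB19 (0.0561) were lost. The transport list of 20 members was not called (adjusted p = 0.977, median -0.06, mean 0.05). Of 25 genes of auxin synthesis and inactivation YUC5 (AT5G43890) (1.25 ± 0.22) and ASA1 (AT5G05730) (0.44 ± 0.08) rose and 0 fell (list adjusted p = 0.221). Of 16 receptors and response factors ARF10 (AT2G28350) fell (-0.47 ± 0.08, list adjusted p = 0.081). Not called were IAA5 (-0.64 ± 0.49, adjusted p = 0.459) and LBD29 (-0.43 ± 0.44, 0.598). Nor were AUX1 (0.09 ± 0.08, 0.542) and TAA1 (0.41 ± 0.20, 0.258).

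Among genes with a mean of at least 2 CPM, AT4G23440 (5.51 ± 0.72), a TIR-NBS disease resistance protein, and AT5G57760 (4.57 ± 0.89) had the largest rises with MT. PAP5 (4.05 ± 0.40), PEPC1 (3.72 ± 0.23), SPX3 (3.19 ± 0.32), AT3G25240 (3.68 ± 0.28) and PP2-B13 (3.34 ± 0.28) rose with MT as with IAA. The NAC transcription factor gene NAP (AT1G69490) (3.87 ± 0.45), the transporter gene ABCC7 (AT3G13100) (3.21 ± 0.41) and AT1G33760 (3.09 ± 0.27) rose as well. AT4G23440 had 15 counts in the control libraries, 1 and 14, and 704 with MT, and its log2 fold change was 8.25 without control replicate 2. AT5G57760 had 5.99 without control replicate 1, NAP 3.196 without MT replicate 1 and ABCC7 2.39 without MT replicate 2. With robust empirical Bayes the calls of AT5G57760 (adjusted p = 0.117) and ABCC7 (0.06025) were lost. ABCC7, AT4G23440, AT5G57760 and PP2-B13 overlap other gene models, so their counts are uncertain.

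The largest falls among genes of at least 2 CPM were those of AT1G02150 (-5.02 ± 0.53) and CAX4 (AT5G01490) (-3.06 ± 0.41), a cation exchanger. XTH25 (AT5G57550) (-2.79 ± 0.52), LHT7 (AT4G35180) (-2.68 ± 0.39), ICME-LIKE2 (AT3G02410) (-2.59 ± 0.38) and the myo-inositol oxygenase MIOX2 (AT2G19800) (-2.59 ± 0.19) came next. The proline dehydrogenase ERD5 (AT3G30775) (-2.41 ± 0.17), AT5G40250 (-2.32 ± 0.20) and AT1G69030 (-2.19 ± 0.34) fell too. Without control replicate 1 CAX4 had -2.41, without MT replicate 1 XTH25 had -3.53, and without MT replicate 2 ICME-LIKE2 had -3.23. Beside CAX4 and AT1G69030 the next gene on the same strand went the other way with MT, from 10.1 to 26.0 CPM at CAX4 and from 5.43 to 22.8 CPM at AT1G69030. The share of reads that each gene of such a pair received is uncertain.

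The MT count was 521 without control replicate 1, 549 without control replicate 2, 1127 and 1081 without IAA replicates 1 and 2, 732 without MT replicate 1 and 1304 without MT replicate 2, and 2905 with DESeq2. Of the 109 named genes called with MT 46 passed with each library left out in turn, and the others reached adjusted p between 0.0515 and 0.184 without at least 1 library.

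**Figure D2:**
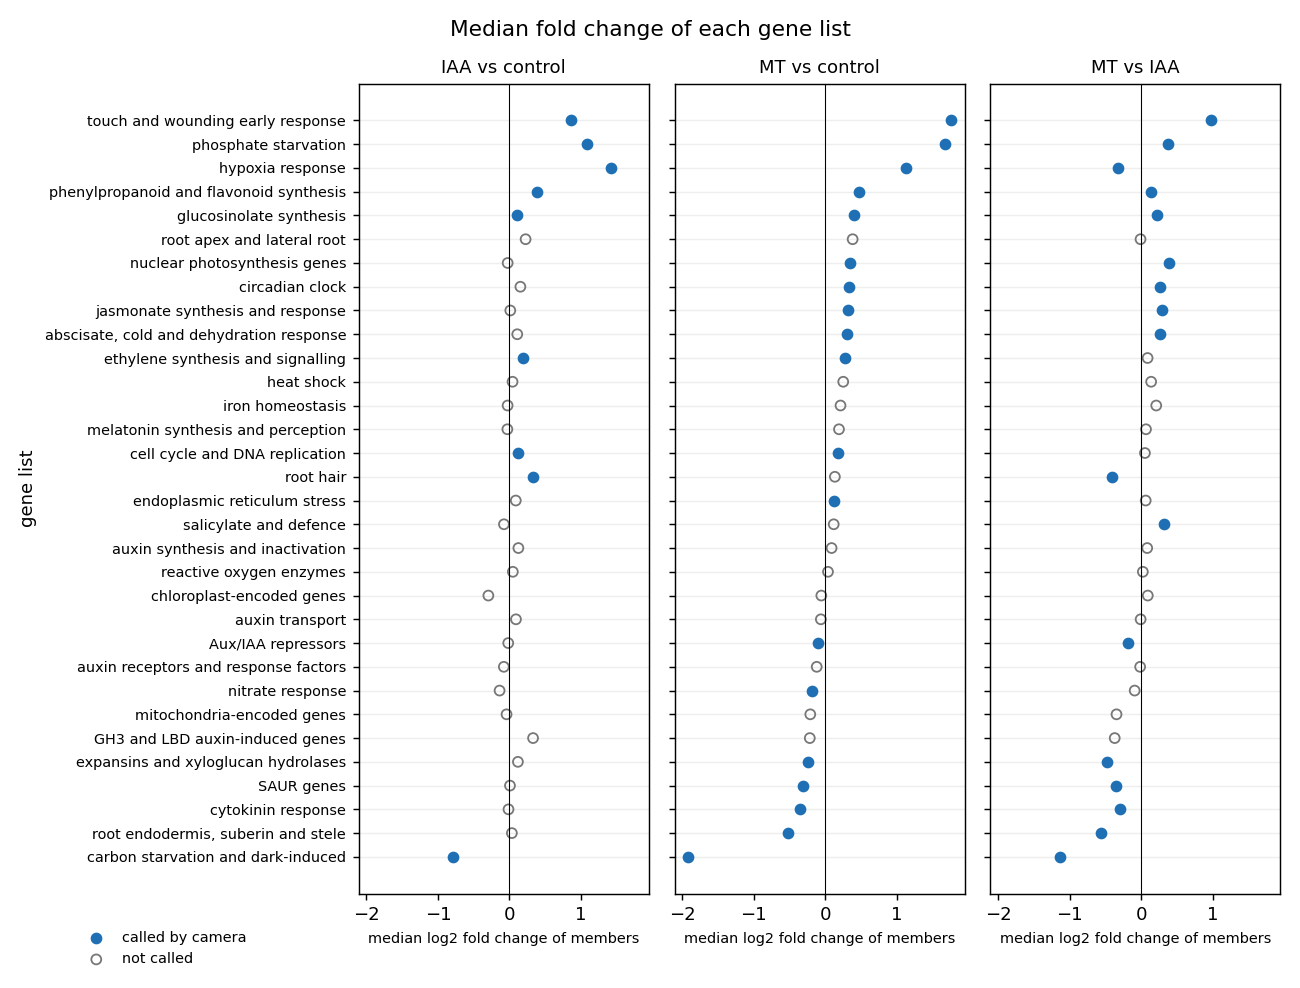
Median log2 fold change of the members of each of the 32 tested gene lists in the 3 comparisons, with filled points for lists called by camera with its preset correlation and open points for the others. With MT against control, touch, phosphate and hypoxia genes stand highest (medians 1.77, 1.68 and 1.13) and carbon starvation genes lowest (-1.92), while with an estimated correlation 0 lists were called in each comparison.

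The third question was how far the responses to IAA and MT ran together and where they differed. Of the 71 genes called with IAA 64 were called with MT, 55 higher in both, 9 lower in both and 0 in opposite directions. Phosphate genes such as SPX1, SPX3, MGDC and PAP17 were among the 55. Independent lists of these sizes would share 2.32 higher and 0.47 lower genes. In 50 simulated pairs of unchanged groups with shared simulated controls, 0.96 genes were shared on average and 4 at most. The simulated groups had 3.86 and 3.4 calls on average, so their lists were too short to share as many genes as the observed lists. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.617 and Spearman's rho of 0.572, beside a simulated r of 0.507 (SD 0.020). The simulated genes were drawn independently, so this SD and that of the covariance leave out correlation between genes. The covariance was 0.180 beside 0.0621 (SD 0.0044) in the simulation, a difference of 0.118. With 1 control library for each comparison, a split chosen after this result was seen, the covariance was 0.102 and 0.0984. That is less than the difference, so part of this excess may come from the shared controls. The split does not remove a deviation that both control libraries have in common. Such a deviation cannot be told apart here from a response common to both compounds. The 64 genes called with both became 18 without control replicate 1, 20 without control replicate 2, 14 without IAA replicate 1 and 8 without IAA replicate 2.

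Tested directly, 19 genes were higher and 18 lower with MT than with IAA, and 31 of these 37 were called against control with MT, 8 with IAA. Phox2 was at 28.2 ± 0.833 CPM with IAA and 132 ± 2.76 with MT, beside 116 ± 15.0 in the control (2.23 ± 0.10, adjusted p = 0.00352, n = 2). ATN (2.19 ± 0.20), CNI1 (AT5G27420) (1.47 ± 0.17), the receptor-like kinase gene CRK10 (AT4G23180) (1.08 ± 0.10) and AT3G04640 (1.12 ± 0.13) were higher with MT. So were AT5G15950 (1.02 ± 0.12), an adenosylmethionine decarboxylase, AT3G23170 (1.02 ± 0.10), LHCB2.3 (0.89 ± 0.11), RBCS3B (0.77 ± 0.09), CYP71B26 (AT3G26290) (0.89 ± 0.09) and AT1G74450 (0.82 ± 0.10). Lower with MT were SDR3 (-5.88 ± 0.66), AT1G02150 (-5.09 ± 0.53), CAX4 (-3.49 ± 0.41), AT5G40250 (-2.13 ± 0.20) and MRN1 (-1.70 ± 0.17). MIOX2 (-1.59 ± 0.19), DIN10 (-1.28 ± 0.10), AT2G23100 (-1.22 ± 0.14), MSRB9 (AT4G21850) (-1.21 ± 0.10) and XTH33 (-1.09 ± 0.11) were lower as well. SDR3 had -7.97 without MT replicate 2, and AT1G02150 had -4.38 without IAA replicate 2. With robust empirical Bayes the calls of CAX4 (adjusted p = 0.0538) and SDR3 (0.05595) were lost. With the replicate number as a block 12 genes were called between MT and IAA. Among the calls then lost were those of ATN, AT1G02150 and MRN1 (adjusted p = 0.0525 each) and RBCS3B (0.0769).

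By list, 9 were higher and 8 lower with MT than with IAA in camera's test. Of these, fry called the carbon starvation list (fry adjusted p = 0.0499) and not the others, among them photosynthesis (0.056) and endodermis (0.123). The photosynthesis list was higher, with 2 of 36 members called over all genes. Its median was 0.39 and, adjusted over the list alone, 31 rose and 0 fell. Camera gave the photosynthesis list an adjusted p of 6.73e-22, and adjusted p = 0.261 with an estimated correlation. Of the other 8 higher lists 0 members passed over all genes. Touch genes had a median of 0.97 (camera adjusted p = 3.53e-06, and adjusted p = 0.261 with an estimated correlation) and, adjusted over the list alone, 9 rose and 0 fell. Clock genes had a median of 0.26 (camera adjusted p = 1.37e-05, and adjusted p = 0.345 with an estimated correlation) and, adjusted over the list alone, 7 rose and 0 fell. Phosphate genes had a median of 0.38 (camera adjusted p = 0.000104, and adjusted p = 0.345 with an estimated correlation) and, adjusted over the list alone, 4 rose and 0 fell. SPX1 had 0.47 ± 0.11. Jasmonate genes had a median of 0.30 (camera adjusted p = 0.000104, and adjusted p = 0.261 with an estimated correlation) and, adjusted over the list alone, 9 rose and 1 fell. Glucosinolate genes had a median of 0.22 (camera adjusted p = 0.000208, and adjusted p = 0.261 with an estimated correlation) and, adjusted over the list alone, 7 rose and 0 fell. Abscisate genes had a median of 0.26 (camera adjusted p = 0.00102, and adjusted p = 0.261 with an estimated correlation) and, adjusted over the list alone, 4 rose and 0 fell. Flavonoid genes had a median of 0.14 (camera adjusted p = 0.0106, and adjusted p = 0.352 with an estimated correlation) and, adjusted over the list alone, 1 rose and 0 fell. Salicylate genes had a median of 0.32 (camera adjusted p = 0.0118, and adjusted p = 0.519 with an estimated correlation) and, adjusted over the list alone, 2 rose and 0 fell. Without MT replicate 2 the adjusted p was 0.0607 for jasmonate and 0.0797 for flavonoid genes, and without IAA replicate 2 it was 0.105 for flavonoid genes. For salicylate genes it was 0.0908 without MT replicate 1 and 0.581 without IAA replicate 1.

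Lower with MT than with IAA was the endodermis list, where MRN1 was the called member of 24. Its median was -0.56 and, adjusted over the list alone, 0 rose and 20 fell. Camera gave the endodermis list an adjusted p of 1.97e-11, and adjusted p = 0.345 with an estimated correlation. DIN10 was the called member of 5 in the carbon starvation list and XTH33 of 23 in the cell wall list. Carbon starvation genes had a median of -1.13 (camera adjusted p = 1.37e-05, and adjusted p = 0.261 with an estimated correlation) and, adjusted over the list alone, 0 rose and 4 fell. Cell wall genes had a median of -0.47 (camera adjusted p = 1.37e-05, and adjusted p = 0.261 with an estimated correlation) and, adjusted over the list alone, 0 rose and 10 fell. In the other 5 lower lists 0 members passed over all genes. Root hair genes had a median of -0.41 (camera adjusted p = 1.37e-05, and adjusted p = 0.352 with an estimated correlation) and, adjusted over the list alone, 1 rose and 9 fell. SAUR genes had a median of -0.35 (camera adjusted p = 0.000106, and adjusted p = 0.345 with an estimated correlation) and, adjusted over the list alone, 0 rose and 0 fell. Hypoxia genes had a median of -0.33 (camera adjusted p = 0.00075, and adjusted p = 0.439 with an estimated correlation) and, adjusted over the list alone, 0 rose and 1 fell. Aux/IAA genes had a median of -0.18 (camera adjusted p = 0.00874, and adjusted p = 0.261 with an estimated correlation) and, adjusted over the list alone, 0 rose and 0 fell. Cytokinin genes had a median of -0.29 (camera adjusted p = 0.0106, and adjusted p = 0.345 with an estimated correlation) and, adjusted over the list alone, 0 rose and 0 fell. In the 13 called lists with 0 such members, higher or lower, 98 of 259 members had an unadjusted p under 0.05 in edgeR's test and DESeq2 called 50. Of all 21355 genes tested 3707 had an unadjusted p under 0.05 between MT and IAA. The other 15 lists were not called, with adjusted p from 0.0587 to 0.807. Calls were lost without MT replicate 2 for Aux/IAA (adjusted p = 0.0531), without MT replicate 1 for hypoxia (0.226) and without IAA replicate 2 for cytokinin genes (0.159).

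Of the 9 sentinels 0 were called between MT and IAA in edgeR's test, at the unmatched doses used, while 3 had an unadjusted p under 0.05 and DESeq2 called 3. The log2 difference was -1.08 for GH3.3 (95% interval -1.53 to -0.63, adjusted p = 0.0945) and -0.75 for IAA19 (-1.27 to -0.24, 0.17). It was -0.95 for IAA5 (-2.09 to 0.18, 0.364) and -0.82 for LBD29 (-1.85 to 0.21, 0.387). PIN7 had 0.70 (0.35 to 1.05, 0.112) and PIN3 -0.24 (-0.49 to 0.01, 0.31). AUX1 had 0.01 (-0.19 to 0.21, 0.967), which turned to -0.0102 with upper quartile factors. TAA1 had 0.13 (-0.34 to 0.61, 0.784) and CCA1 0.25 (-0.25 to 0.75, 0.594). Intervals that include 0 do not show that the compounds acted alike.

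The count of 37 genes was 7 without control replicate 1, 6 without control replicate 2, 13 without IAA replicate 1, 7 without IAA replicate 2, 34 without MT replicate 1, 333 without MT replicate 2 and 1225 with DESeq2. Of the 25 named genes called between MT and IAA, Phox2 passed with each library left out, and the others reached adjusted p from 0.0918 to 0.233 without at least 1 library.

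**Figure D3:**
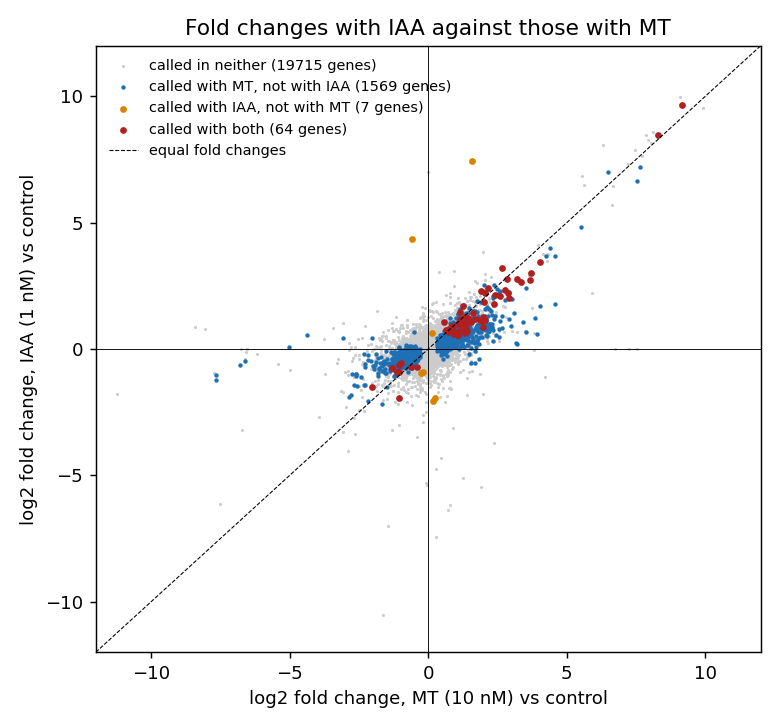
Log2 fold change of each of the 21355 tested genes with IAA (vertical axis) against that with MT (horizontal axis), both against the same 2 control libraries, coloured by where the gene was called, with equal fold changes as a dashed line. The 64 genes called with both lie in the quadrants of equal sign.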

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

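All but 1 of the tests in this part, that of overlapping gene models, were chosen after the result was seen.

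Between MT and IAA 9 called genes had opposite signs against control. Higher with MT and lower with IAA were Phox2 (log2 difference 2.23), ATN (2.19), CYP89A2 (AT1G64900) (0.79) and AT5G17760 (0.69). Lower with MT and higher with IAA were AT1G02150 (-5.09), AT5G01881 (-4.96), CAX4 (-3.49), MSRB9 (-1.21) and AT1G15670 (-0.83). Against control Phox2, ATN and AT5G01881 were called with IAA, 5 others with MT, and AT5G17760 with neither, so opposite directions against control were not themselves shown for any of them. AT5G01881 overlaps another gene model and rests on 6 counts with MT against 240 with IAA, and its difference was -6.52 without MT replicate 1. That of AT1G02150 was -4.38 without IAA replicate 2, and with upper quartile factors the call of AT5G17760 was lost (adjusted p = 0.05505). Of the 9, Phox2 kept its call with each library left out, at 116 ± 15.0 CPM in control, 28.2 ± 0.833 with IAA and 132 ± 2.76 with MT.

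Called genes of at least 2 CPM that changed at least 8-fold in a comparison numbered 15, among them SDR3, AT1G02150, CAX4, ABCC7, PAP5, PEPC1 and SPX3. Not all were near absent in a group: PEPC1 had 5.37 CPM in the control and 71.0 with MT. Reads shared with an overlapping gene could produce such large changes, but 5 of the 15 (33.3%) overlapped another gene model against 5755 of 18094 tested genes of at least 2 CPM (31.8%, exact Fisher test, two-sided, p = 1), too few to exclude a smaller excess. Reads moved between neighbours on the same strand could also produce them. Counts of a pair were taken to cancel where the SD of the summed CPM was under 0.5 of the smaller member's SD. By that rule 1 of the 15, CAX4, had such a neighbour, not most of the set as that explanation predicted. A neighbour with a much larger spread or under 2 CPM cannot meet the rule, so moved reads are not excluded for the others. For CAX4 itself that explanation cannot be told apart from a change in CAX4: its sum with the neighbour was 22.6, 24.6 and 27.5 CPM in control, IAA and MT, a log2 change of 0.28 with MT, but the pair was picked because its counts cancel. A response of these genes to the compounds stays open.

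Pairs whose counts cancelled made up 44 of 8060 adjacent genes on the same strand (0.546%), against 13 of 7674 on opposite strands (0.169%, exact Fisher p = 8.44e-05) and 13 of 7995 on the same strand with 1 gene between (0.163%, exact Fisher p = 4.61e-05). They held 10 of the 1633 genes called with MT, 0 of the 71 called with IAA and 1 of the 37 called between MT and IAA.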

How the results depend on the processing

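All alternatives were planned. Relative log expression and upper quartile factors and leaving out organelle-encoded genes kept each count of genes within 1.5 times, as did relative log expression factors for lists, which were not run with the others. For genes called with IAA against control (71), robust empirical Bayes gave 130, DESeq2 768, a 2-fold minimum 42, an adjusted p threshold of 0.1 155 and the 2 groups alone 125, with 14 to 120 over libraries left out. For MT against control (1633), DESeq2 gave 2905, the 2-fold minimum 455, the threshold of 0.1 3102 and libraries left out 521 to 1304. For MT against IAA (37), no filter gave 76, robust 142, DESeq2 1225, the 2-fold minimum 19, the threshold of 0.1 283, the 2 groups alone 6 and libraries left out 6 to 333. Genes called with both compounds (64) were 115 with robust, 550 with DESeq2 and 8 to 95 over libraries left out. The correlation of effects (0.617) was 0.572 with no filter, 0.647 with the CPM filter, 0.556 with DESeq2 and 0.485 to 0.770 over libraries left out. The DESeq2 calls included 71 of the 71, 1623 of the 1633 and 36 of the 37. A stricter threshold gives fewer calls and a looser threshold more by construction, and for the other settings and the libraries left out the cause was not tested. Lists called fell to 0 in each comparison with an estimated correlation and to 2 (IAA) and 1 (MT against IAA) with fry, and were 7 to 10, 17 to 21 and 15 to 18 over libraries left out. Signs turned for 5 sentinels, with 0 of them called in the fits that turned them. With IAA, IAA5 had -0.15 without control replicate 1, in a range of -0.15 to 0.99 over libraries left out. With MT, IAA5 had 0.042 without control replicate 2 (range -1.10 to 0.042) and LBD29 0.038 without control replicate 1 (-0.79 to 0.038). CCA1 had 0.11 without MT replicate 2 (-0.62 to 0.11, the first without MT replicate 1 and called). Between MT and IAA the turns came without MT replicate 1: AUX1 -0.069 (to 0.086), CCA1 -0.15 (to 0.57) and TAA1 -0.12 (to 0.36). AUX1 also turned with upper quartile factors (-0.0102). No called gene that the text names changed sign with a library left out. The labels state no pairing by replicate number, and the correlations of deviations were low (0.0254 for control and IAA, 0.0074 for control and MT, 0.079 for IAA and MT). With 2 libraries per group such values cannot exclude a pairing by replicate number. With the number as a block (replicate block) 48, 1325 and 12 genes were called and 44 with both compounds, and 41 calls of named genes were lost. Among those lost with IAA were PAP5 (adjusted p = 0.0531), ACO1 (0.0561), LHCB1.2 (0.0701) and LHCB3 (0.0851). Among those lost with MT were CDKB2;2 (0.0752), NIA2 (0.0773) and COR15A (0.0612). With 2 libraries per group, changes of 1.5-fold were mostly missed at these depths in the simulated data.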

Other observations

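All tests of explanations in this part but that of harvest time were chosen after the result was seen.

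The jasmonate and dehydration lists were called higher with MT than control, calls that were lost with an estimated correlation, and most of their members did not pass. In the jasmonate list 7 of 26 measured members rose, 1 fell and 18 did not pass. Its median was 0.33 and, adjusted over the list alone, 11 rose and 2 fell. Camera gave the jasmonate list an adjusted p of 0.0103, and adjusted p = 0.386 with an estimated correlation. LOX4 (AT1G72520), a lipoxygenase of jasmonate synthesis, rose by 2.15 ± 0.18, the defensin PDF1.2 (AT5G44420) by 0.94 ± 0.15 and MYC2 (AT1G32640) by 0.51 ± 0.09, while the repressor gene TIFY7 (AT1G70700) fell (-0.66 ± 0.10). In the list of abscisate, cold and dehydration response 5 of 24 measured members rose, 2 fell and 17 did not pass. Its median was 0.31 and, adjusted over the list alone, 10 rose and 2 fell. Camera gave the abscisate list an adjusted p of 0.0103, and adjusted p = 0.203 with an estimated correlation. LTI78 (AT5G52310) (0.74 ± 0.13), COR15B (AT2G42530) (0.99 ± 0.18), COR15A (AT2G42540) (0.92 ± 0.21), P5CS1 (AT2G39800) (0.49 ± 0.10) and the phosphatase gene ABI1 (AT4G26080) (0.80 ± 0.15) rose and HAB1 (AT1G72770) (-0.44 ± 0.08) and RAB18 (AT5G66400) (-0.58 ± 0.13) fell. Of 23 salicylate and defence genes CBP60G (AT5G26920) (1.59 ± 0.20) and SAG101 (AT5G14930) (0.56 ± 0.11) rose, and adjusted over the list alone, 6 rose and 2 fell (list adjusted p = 0.163). The oxidase gene RBOHD (AT5G47910) rose with IAA (0.81 ± 0.08) and with MT (1.38 ± 0.08), in a list of 26 reactive oxygen enzymes that was not called (adjusted p = 0.352 with MT). In the same list CAT3 (AT1G20620) rose with MT (0.94 ± 0.11) and CAT1 (AT1G20630) fell (-0.31 ± 0.07). The call of CAT1 was lost with relative log expression factors (adjusted p = 0.0521) and with no filter (0.0529). Without MT replicate 2 the adjusted p of the jasmonate list was 0.328, and without control replicate 2 that of the abscisate list was 0.0611.

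With MT 2 of 11 genes of nitrate response fell, LBD39 (AT4G37540) (-0.55 ± 0.09) and NIA2 (AT1G37130) (-0.48 ± 0.10). The nitrate list had a median of -0.19 and, adjusted over the list alone, 0 rose and 3 fell. Camera gave the nitrate list an adjusted p of 0.0218, and adjusted p = 0.247 with an estimated correlation. Of 16 cytokinin response genes 1 fell, ARR4 (AT1G10470) (-0.71 ± 0.12). The cytokinin list had a median of -0.36 and, adjusted over the list alone, 0 rose and 1 fell. Camera gave the cytokinin list an adjusted p of 0.041, and adjusted p = 0.421 with an estimated correlation. Of 8 genes of endoplasmic reticulum stress 1 rose, BZIP60 (AT1G42990) (0.43 ± 0.08). The endoplasmic reticulum list had a median of 0.13 and, adjusted over the list alone, 1 rose and 0 fell. Camera gave the endoplasmic reticulum list an adjusted p of 0.00884, and adjusted p = 0.203 with an estimated correlation. Of 24 cell cycle genes 1 rose, CDKB2;2 (AT1G20930) (0.70 ± 0.16). The cell cycle list had a median of 0.17 and, adjusted over the list alone, 0 rose and 0 fell. Camera gave the cell cycle list an adjusted p of 0.0077, and adjusted p = 0.534 with an estimated correlation. The iron regulator BHLH101 (AT5G04150) rose (4.03 ± 0.88) in a list of 19 that was not called (adjusted p = 0.0728). It had 5 counts in the control and 87 in the MT libraries, a ratio of 17.1 (95% counting interval 7.06 to 54.0). In edgeR's test 0 members passed with MT among the 5 genes of melatonin synthesis and perception (list adjusted p = 0.266; 1 with an unadjusted p under 0.05 and 1 called by DESeq2), 11 heat shock genes (0.63; 2 and 1), 16 root apex genes (0.217; 4 and 0), 17 root hair genes (0.977; 1 and 0), 58 chloroplast-encoded (0.677) and 41 mitochondria-encoded genes (0.246). Of all 21355 genes tested 5381 had an unadjusted p under 0.05 with MT. Calls were lost without control replicate 1 for nitrate (adjusted p = 0.064) and cytokinin (0.0868), without MT replicate 1 for cytokinin (0.0811) and without MT replicate 2 for the cell cycle (0.199).

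The rise of the clock list with MT, a call lost with an estimated correlation (adjusted p = 0.474), has a candidate explanation in harvest at another time of day. Evening-phased genes had a median log2 fold change of 0.62 with MT and 5 of 7 rose, among them ELF4 (AT2G40080) (0.62 ± 0.14) and PRR5 (AT5G24470) (0.60 ± 0.10), while the 8 morning-phased genes had a median of -0.25, a difference of 0.868 (SD of the members 0.785). This split against control is what a shift of harvest time predicts, although the morning genes LNK1 (AT5G64170) (1.28 ± 0.25, called) and PRR9 (AT2G46790) (1.53 ± 0.41, adjusted p = 0.0687) stood higher too. With IAA against control the evening and morning medians were 0.25 and -0.39, a difference of 0.645 (SD of the members 0.452). The predicted split was thus seen with IAA too, although the list was not called there (camera adjusted p = 0.62). Both comparisons used the same 2 control libraries. Between MT and IAA the list was called higher with MT too (adjusted p = 0.345 with an estimated correlation). There the medians were 0.37 and 0.26, a difference of 0.113 (SD of the members 0.440), so the predicted split was not seen. Harvest time stays open for IAA and for MT against control, as does an effect of the compounds on the clock itself.

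Photosynthesis genes stood higher and endodermis genes lower with MT than control, calls that were lost with an estimated correlation (adjusted p = 0.34 and adjusted p = 0.474). A smaller share of root tissue may be considered, which would lower all lists of root genes alike if their genes are confined to roots. The root apex list had a median of 0.38 (SD of members 0.417) and the endodermis list of -0.52 (SD 0.471), a difference of 0.905 with a permutation p of 0.0001, which is too small since endodermis members were correlated (0.703), and the root hair list had 0.14 (SD 0.624). Per library, against the mean of the control libraries, this difference was 0.79 and 0.78 with MT and 0.14 and 0.13 with IAA. In control it was 0.0033 and -0.0033, values that mirror each other by construction. The medians themselves were 0.20 and -0.20 in control replicates 1 and 2, for root apex and endodermis alike, and 0.19 and -0.19 for root hair. In MT replicates 1 and 2 they were 0.37 and 0.24 for root apex, -0.42 and -0.54 for endodermis, and -0.06 and 0.17 for root hair. Between MT and IAA the medians were -0.0072 (root apex), -0.56 (endodermis) and -0.41 (root hair, SD 1.59), so root hair genes stood lower there, as with a smaller root share, and root apex genes did not, but 0 of 17 root hair genes passed and that list's call was lost with an estimated correlation (adjusted p = 0.352). The root apex list did not fall with the endodermis list, so an equal fall of all root lists was not seen. The root apex list was itself not called with MT (camera adjusted p = 0.217), and whether its genes are confined to roots was not tested. A smaller root share therefore stays open, as does a change within the endodermis or the response of these genes to MT.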
